A study of Mus musculus with 6 samples.

How the data were processed

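RNA-seq had been run on 6 libraries of NIH3T3 mouse fibroblasts, 2 after PBS, 2 after MCF10A EVs and 2 after MDA-MB-231 EVs. Per the labels, the cells were at passage 5, RNA was extracted with TRIzol 48 h after treatment and libraries were made with a stranded mRNA kit. Which strand was counted, the read counter, the annotation and the versions are not given in the sources used here. Per the labels, the authors used TopHat2 and edgeR and named the human build hg19, whereas the table names mouse genes by mouse chromosome. The mouse build is therefore unknown, and genes are located by chromosome only.

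The authors deposited a table of normalised signal for 20475 genes and 6 libraries. Its values are edgeR quantile-adjusted pseudo-counts, that is, reads adjusted to a common library size within the 3 groups, in reads and not whole. Whole reads were recovered by inverting that adjustment with 5 free relative library sizes and a common dispersion of 0.000591, a coefficient of variation of 2.43%. All 122850 values, 100.0%, came from whole reads within a relative 1e-06, and the largest relative difference was 1.57e-08, also with edgeR's own function. On simulated tables the recovery returned 122850 of 122850 values. The adjustment uses the group labels, so it was undone in the alternatives that count reads. The library totals of the recovered reads ran from 22451173 to 29315530. A floor of 3 reads, taken as an approximate upper bound on the mean behind a count of 0, was 0.102 to 0.134 CPM (counts per mega-read). Such floors and the SDs cover counting error and the spread between these libraries only.

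The groups, comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined. That plan named tests for counts and for normalised values such as CPM, not for pseudo-counts, and its branch for normalised values was used. limma 3.58.1 (lmFit, then eBayes with trend) in R 4.3.3 was run on log2 of the value plus 1, for 15025 genes with at least 1 normalised read in at least 2 libraries. One model with a mean per group was fitted to all 6 libraries, with 3 residual and 11.5 prior degrees of freedom, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. The same comparisons were run on the recovered reads with edgeR 4.0.16 (quasi-likelihood, TMM, 12352 genes), which called 5554, 5160 and 2987 genes for MDA-MB-231 EVs against PBS, MCF10A EVs against PBS and MDA-MB-231 against MCF10A EVs.

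Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, which asks whether a list's members move one way and compares no lists. There were 31 lists with 709 entries, of which 691 matched the table's symbols, 2 of them through other symbols. They covered contractile and myofibroblast genes, TGF-beta response, collagens and fibrillar matrix, matrix proteases and inhibitors, inflammatory cytokines and NF-kB, and interferon response. They also covered mitosis, DNA replication, MYC targets and ribosome biogenesis, ribosomal proteins, glycolysis, hypoxia, oxidative phosphorylation, cholesterol synthesis, fatty acid and lipid handling, and amino acid metabolism. The others were unfolded protein and integrated stress response, heat shock, p53, NRF2, immediate early and MAPK output, YAP and SRF targets, angiogenic and growth factors, autophagy and lysosome, vesicle biogenesis, and epithelial, macrophage and leukocyte, endothelial, adipocyte, and muscle and neural markers. A list of mitochondrially encoded genes matched 0 entries, and 30 lists with at least 5 tested members were tested. Lists share members, such as Pdk1 in glycolysis and hypoxia.

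Named genes were, for each comparison, the 8 called higher and the 8 called lower with the largest change among genes with a mean of at least 5 CPM and libraries that did not overlap between the groups. Predicted genes and symbols ending in Rik were counted but not named. From each list that camera called, up to 4 members with the smallest p were added, and from the others up to 2 called members. Acta2, Col1a1, Il6, Ccl2, Myc, Slc2a1, Mki67 and Isg15 were always given. The rule named 179 genes, and the report gives the main ones. Some genes are counted in their lists but not reported here by name. Reads of near-identical families, such as histones and ribosomal proteins, are uncertain where pseudogenes or paralogs share sequence. Of 20475 genes 4267 had 0 reads, 4 symbols occurred more than once, and 96.0% of the symbols were found in the mouse annotation, which was used for names, GC content and length only.

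The tests were run on simulated data with the real library sizes and spread. For MDA-MB-231 EVs against PBS, of 50 genes each changed 1.25-, 1.5-, 2- and 4-fold, limma called 35, 47, 50 and 50 with the right sign, with 3 false calls among 14756 unchanged genes, and edgeR called 39, 50, 50 and 50, with 9 among 12142. For MDA-MB-231 against MCF10A EVs limma called 35, 47, 50 and 50, with 5 false calls. With no change planted between MCF10A EVs and PBS limma called 0 of 14956 genes. A DNA replication list changed 1.3-fold was called by camera, and 0 of the other lists were. Each gene was drawn independently, so this does not show how often camera calls unchanged lists whose members vary together. Both EV effects were also compared with 50 simulations of unchanged groups that shared the PBS libraries, again with each gene drawn independently.

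The alternatives chosen beforehand were quantile scaling, no filter, a filter of 5 normalised reads, limma without trend, a pseudocount of 0.1, the replicate number as a block, only the 4 libraries compared, leaving out each library, a 2-fold minimum, the estimated correlation and fry. Where a library was left out, the lone sample of its group was assumed to vary like the others. Alternatives chosen after seeing the data were edgeR on the recovered reads with TMM, with DESeq2's size factors, with library totals or with the replicate block, DESeq2 1.42.0, limma-voom, filters of 10 normalised reads and 5 CPM, the estimated correlation with the block, removal of trends on GC content, length and level, a different PBS library for each EV treatment, the distance of list medians from all tested genes with an interval from resampled members, and 7 further gene lists. Across groups, libraries with the same replicate number shared no signal, with correlations of their deviations of -0.00648, -0.00442 and 0.0188 over 10309 genes, so the numbers were not read as pairs. Replicates differed by more than counting noise, with a chi-squared per gene of 1.66, 2.29 and 2.11 in the PBS, MCF10A EV and MDA-MB-231 EV groups. Figures and the recovery used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.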

Results

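The data were RNA-seq gene read values from 6 libraries of NIH3T3, a mouse embryonic fibroblast line. Each library came from cells that had received extracellular vesicles (EVs), the membrane-bound particles that cells release, or the phosphate-buffered saline (PBS) in which the EVs were suspended. There were 2 libraries after PBS, 2 after EVs from MCF10A, a non-tumorigenic human breast epithelial line, and 2 after EVs from MDA-MB-231, a human triple-negative breast cancer line. RNA was extracted 48 h after treatment. The libraries held 23279661 and 27000816 gene reads with PBS, 23126453 and 29315530 with MCF10A EVs, and 23945284 and 22451173 with MDA-MB-231 EVs. Between 14553 and 14856 genes had a read in a library, and the 10 most abundant genes took 4.62% to 5.62% of its reads. The labels do not state that the replicates were separate cultures, so the p-values measure the spread between these samples only.

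On the first principal component, which held 67.3% of the variance of 10309 genes, the PBS libraries lay at -16.7 and -16.4, the MCF10A EV libraries at 3.27 and 4.81, and the MDA-MB-231 EV libraries at 12.2 and 12.8. The second component, with 20.7%, set the MCF10A EV libraries at -9.44 and -9.10 apart from the PBS libraries at 2.48 and 2.95 and the MDA-MB-231 EV libraries at 5.41 and 7.70. Gene levels are given as normalised reads, mean ± SD, with n = 2 libraries per group. Rose and fell refer to limma calls at an adjusted p under 0.05. Members of a list that are named for a count of 5 or fewer, and are not among the named genes, were chosen after their values were seen.

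**Figure D1:**
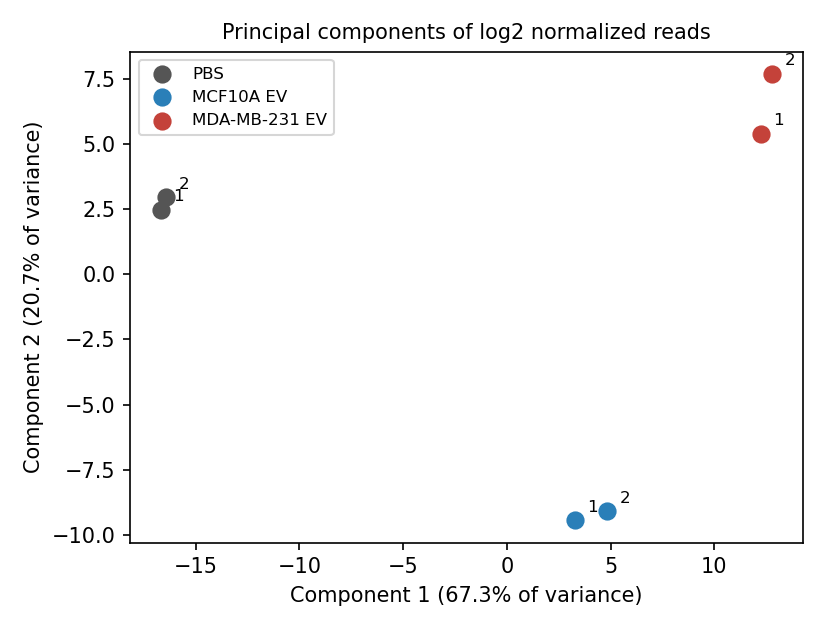
Principal components of the log2 normalised reads of 10309 genes, with component 1 (67.3% of the variance) on the horizontal and component 2 (20.7%) on the vertical axis, and a point for each of the 6 libraries, coloured by treatment. The PBS libraries lie at -16.7 and -16.4 on component 1, and all 4 EV libraries lie between 3.27 and 12.8.

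The comparison of MDA-MB-231 EVs with PBS asks which fibroblast transcripts differ after vesicles of a breast cancer line. With MDA-MB-231 EVs, transcripts of inflammatory mediators and of the immediate early and MAPK response fell, and those of cell division rose. Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, fell from 128820 ± 115 to 31472 ± 2503 normalised reads, 4.10-fold. Il6, which encodes interleukin-6, fell from 1986 ± 121 to 461 ± 29.5, 4.30-fold, and Lif, a cytokine of the same family, fell from 30632 ± 619 to 8192 ± 582, 3.74-fold. Nr4a1, an immediate early nuclear receptor gene, fell 3.58-fold from 14855 ± 155 to 4151 ± 186. Mki67, a marker of proliferating cells, rose 1.42-fold from 15818 ± 592 to 22375 ± 117.

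Of the inflammatory and NF-kB list, 20 of 30 measured members fell and 2, Cxcl12 and Ccl7, rose, with a median log2 change of -0.49 (camera adjusted p = 2.35e-12, adjusted p = 0.198 with an estimated correlation). Cxcl1, a neutrophil chemokine, fell 2.20-fold to 16627 ± 444, and Ccl2, a monocyte chemokine, fell from 38811 ± 104 to 28498 ± 313. Beside these, the macrophage markers Cd14 and Csf1r fell, Cd14 from 2992 to 977 and Csf1r from 78.5 to 27.6 normalised reads. In the immediate early and MAPK list, 23 of 26 members fell and 0 rose, with a median of -0.75 (camera adjusted p = 4.09e-17, adjusted p = 0.198 with an estimated correlation). Ier3 fell 2.75-fold, Egr1 2.29-fold, and Spry2, a feedback inhibitor of receptor tyrosine kinase signalling, 2.13-fold.

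Members of the hypoxia list fell in 12 of 19 cases, and 2, Lox and Adm, rose (camera adjusted p = 1.56e-08, adjusted p = 0.198 with an estimated correlation). Vegfa, the angiogenic growth factor, fell 2.66-fold from 14930 ± 95.3 to 5614 ± 34.1, and Bnip3, a mitophagy receptor, fell 1.72-fold. Of 23 glycolysis and glucose uptake genes, 16 fell, among them Pgk1 and Pdk1, and Slc16a1 and Ldhb rose (camera adjusted p = 8.56e-08, adjusted p = 0.198 with an estimated correlation). Slc2a1, the glucose transporter, fell from 6960 ± 177 to 5346 ± 242. Cholesterol synthesis genes fell in 15 of 20 cases, with Msmo1 1.38-fold and Fdps 1.42-fold lower, and 1 rose (camera adjusted p = 5.08e-09, adjusted p = 0.198 with an estimated correlation). Of 25 genes of the unfolded protein and integrated stress response, 24 fell and 0 rose, with a median of -0.54 (camera adjusted p = 4.50e-23, adjusted p = 0.198 with an estimated correlation). The endoplasmic reticulum chaperone Hspa5 fell 1.69-fold from 58146 ± 383 to 34450 ± 1824, and its partner Hyou1 fell 1.76-fold.

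All 25 mitotic genes rose, with a median of 0.44, and Bub1b, a spindle checkpoint kinase, was 1.54-fold higher (camera adjusted p = 6.52e-20, adjusted p = 0.101 with an estimated correlation). All 26 DNA replication genes rose, with a median of 0.48 (camera adjusted p = 8.62e-20, adjusted p = 0.0765 with an estimated correlation). The helicase subunit genes Mcm3, Mcm4 and Mcm6 rose 1.52-fold, 1.52-fold and 1.52-fold, and Mcm5 rose 1.56-fold. Of 27 genes of MYC targets and ribosome biogenesis, 22 rose, among them Dkc1 at 1.64-fold and Ncl, which encodes nucleolin, at 1.31-fold (camera adjusted p = 3.46e-09, adjusted p = 0.198 with an estimated correlation). The 4 that fell were Mxi1 and Mxd4, whose products antagonise MYC, and Odc1 and Myc. Myc fell from 1566 ± 13.5 to 1420.3 ± 33.7 (limma, adjusted p = 0.0168), a call lost without PBS replicate 1, PBS replicate 2 or MDA-MB-231 EV replicate 2, where its log2 change was -0.15, -0.13 and -0.12. It was also lost with library totals, at -0.075 (adjusted p = 0.169), with DESeq2 (adjusted p = 0.0726) and by limma without trend (adjusted p = 0.089).

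Collagens and other fibrillar matrix genes fell in 22 of 33 cases and 3, Col3a1, Lox and Bgn, rose (camera adjusted p = 3.00e-08, adjusted p = 0.322 with an estimated correlation). Tnc, which encodes tenascin-C, fell 2.35-fold from 124510 ± 120.2 to 52936 ± 2834, Thbs1 fell 2.02-fold, and Col1a1 fell from 56642 ± 662 to 48206 ± 1478. Matrix proteases and inhibitors fell in 13 of 20 cases, led by the collagenase gene Mmp13 at 4.63-fold, and Adamts5 rose (camera adjusted p = 6.52e-07, adjusted p = 0.198 with an estimated correlation). Of 20 TGF-beta response genes, 11 fell, such as Tgfbi and Inhba, and 4 rose (camera adjusted p = 0.0241, adjusted p = 0.198 with an estimated correlation). Those that rose were Id1, Id2 and Id3, inhibitors of basic helix-loop-helix factors, and Smad6, an inhibitory SMAD gene. Angiogenic and growth factors fell in 13 of 24 cases and Figf rose (camera adjusted p = 1.27e-04, adjusted p = 0.198 with an estimated correlation). Autophagy and lysosome genes fell in 13 of 27 cases and Atg7 rose, with a median of -0.06 that turned to 0.003 when the reads were scaled by library totals (camera adjusted p = 7.96e-04, adjusted p = 0.301 with an estimated correlation). Extracellular vesicle biogenesis genes fell in 11 of 24 cases, among them the tetraspanins Cd9, Cd81 and Cd82, and Flot1 and Rab35 rose (camera adjusted p = 0.00128, adjusted p = 0.198 with an estimated correlation).

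The 8 largest falls were in Plek on chromosome 11, Tnn, Igfbp5, Gpr35 and Ptgs2 on chromosome 1, Stfa3 on chromosome 16, Mmp13 on chromosome 9 and Il6 on chromosome 5. They ranged from 10.5-fold in Plek, which encodes pleckstrin and fell from 261 ± 7.80 to 23.9 ± 0.643, to 4.10-fold in Ptgs2. The 8 largest rises were in Nr1h5, Dctd, Cxcl12, Tfap4, Sned1, Prss23, Amotl2 and Plscr2, from 2.70-fold in Nr1h5 to 1.97-fold in Plscr2. Cxcl12, a chemokine gene on chromosome 6, rose from 87.9 ± 0.102 to 198 ± 26.8. Acta2, which encodes smooth muscle actin, rose from 1500.4 ± 149 to 1919 ± 23.5, but was not called by limma without trend (adjusted p = 0.0572). Isg15, an interferon-induced gene, fell from 46.6 ± 2.85 to 26.0 ± 0.870 (limma, adjusted p = 0.0226). Its call was lost without either PBS or either MDA-MB-231 EV library, where its log2 change lay between -0.88 and -0.76, and with DESeq2 (adjusted p = 0.121).

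Among lists not called by camera, with adjusted p from 0.0522 to 0.844, oxidative phosphorylation had 13 of 33 members higher and Ndufa1, Ndufa2 and Cox6a1 lower. Of 24 fatty acid and lipid genes 9 fell, with the lipase gene Lpl 3.15-fold lower, and Fabp5, Acaca and Fasn rose. Of 20 amino acid genes 12 fell, and Phgdh, Shmt1, Shmt2, Slc7a11 and Psat1 rose. In the contractile list Acta2, Cnn2 and Tpm2 rose and Vim, Pdpn, Thy1, Tpm1 and Des fell, and the median and mean were above 0 while the test pointed down. Under quantile scaling the change of Vim was 0. That scaling gives a gene of the same rank in every library the same value, so this 0 cannot decide on Vim. Of 36 interferon genes 6 rose and 5, H2-D1, H2-K1, B2m, Rsad2 and Isg15, fell, and the median turned from -0.06 to 0.01 with library totals. Ribosomal protein genes included Rpl8 and Rpl27 as higher and 7 lower, with a median of -0.03 that turned to 0.03 under quantile scaling and 0.04 with library totals. Of 14 heat shock genes 6 rose and Hsph1, Bag3 and Hspa4l fell, and the median and mean, just below 0, differed in sign from the test and from the median under every other scaling. Of 21 p53 targets 7 rose, and Cdkn1a, Plk2, Sesn2, Mdm2 and Trp53inp1 fell. NRF2 targets Nqo1, Gsta4, Ftl1, Slc7a11 and Gclm rose and Srxn1, Sod2 and Tkt fell. Of 20 YAP and SRF targets 8 rose and 6 fell, with a median of 0.02 that turned to -0.02 with TMM and -0.03 with DESeq2's size factors.

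Many markers of other cell types had few or no reads, but some were abundant, such as Tjp1 at 4412 and Ncam1 at 1252 normalised reads with PBS. Members without at least 1 normalised read in at least 2 libraries were not tested. Of 10 tested epithelial markers Cdh1 alone was called higher, at 3.11 normalised reads against 0 with PBS, close to the floor of 3 reads. Of 6 macrophage and leukocyte markers Cd14 and Csf1r were the 2 called, both lower. Of 10 endothelial markers Esam rose, from 1.49 to 7.30, and Cdh5 fell, from 347 to 160.0. Of 6 adipocyte markers Lipe fell, and of 9 muscle and neural markers Ncam1, Map2 and Nes rose and Des fell.

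In all, limma called 5231 of 15025 genes between MDA-MB-231 EVs and PBS, 2688 higher and 2543 lower, of which 320 differed at least 2-fold, 78 higher and 242 lower. Without MDA-MB-231 EV replicate 1 or MDA-MB-231 EV replicate 2 the higher of these were 52 and 46. With a filter of 5 CPM those of at least 2-fold were 7 higher and 91 lower, and with DESeq2 they were 19 and 149. Limma without trend called 3346 genes in all. Scaling by library totals gave 4148 higher and 1955 lower, 68.0% higher in place of 51.4%. Adjusted over the list alone, the counts of the called lists were the same as over all genes, except for 6 higher and 11 lower TGF-beta response genes, 25 lower stress genes, 1 higher and 23 lower immediate early genes, 2 higher and 14 lower growth factors, 3 higher and 13 lower autophagy genes and 2 higher and 12 lower vesicle genes. With the preset correlation camera called 15 of 30 lists, and with an estimated correlation 0, with 5 at an unadjusted p under 0.05, while fry called 19.

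The comparison of MCF10A EVs with PBS asks the same of vesicles from a non-tumorigenic breast line. With MCF10A EVs, hypoxia-inducible, glycolytic and cholesterol synthesis transcripts fell, and those of DNA replication, cell division and ribosome biogenesis rose. Vegfa fell 2.26-fold, from 14930 ± 95.3 to 6606 ± 27.2 normalised reads, and Bnip3 fell 2.47-fold, from 5065 ± 170.2 to 2049.7 ± 37.9. The acute phase gene Saa3 fell 2.58-fold, from 22356 ± 1051 to 8656 ± 115. Mcm3 rose 1.44-fold, from 3242 ± 52.1 to 4677 ± 40.1, and Mki67 rose 1.24-fold to 19685 ± 459.

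Hypoxia genes fell in 17 of 19 cases, with a median log2 change of -0.66, and Adm alone rose (camera adjusted p = 1.04e-17, adjusted p = 0.206 with an estimated correlation). Glycolysis and glucose uptake genes fell in 16 of 23 cases and 0 rose (camera adjusted p = 2.13e-12, adjusted p = 0.206 with an estimated correlation). Pdk1, a kinase that inhibits pyruvate dehydrogenase, fell 2.07-fold, Pfkl fell 1.61-fold and Slc2a1 fell from 6960 ± 177 to 5062 ± 44.2. Cholesterol synthesis genes fell in 16 of 20 cases, with Idi1 1.38-fold and Insig1 1.38-fold lower, and 0 rose (camera adjusted p = 8.09e-12, adjusted p = 0.206 with an estimated correlation).

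DNA replication genes rose in all 26 cases, with a median of 0.40 (camera adjusted p = 3.23e-19, adjusted p = 0.0771 with an estimated correlation). Mitotic genes rose in 24 of 25 cases, with Top2a 1.21-fold and Kif11 1.26-fold higher (camera adjusted p = 5.84e-16, adjusted p = 0.141 with an estimated correlation). Of 27 genes of MYC targets and ribosome biogenesis, 24 rose, with a median of 0.42, and the 2 that fell were the MYC antagonists Mxi1 and Mxd4 (camera adjusted p = 6.52e-16, adjusted p = 0.206 with an estimated correlation). Dkc1 rose 1.83-fold and Nop56 1.49-fold, both of them nucleolar factors, whereas Myc itself stood at 1566 ± 13.5 and 1624 ± 48.4 (limma, adjusted p = 0.392). Ribosomal protein genes fell in 9 of 33 cases and 0 rose, with Rpl10 1.11-fold lower (camera adjusted p = 0.00537, adjusted p = 0.534 with an estimated correlation). That camera call was lost under quantile scaling and by fry, with an adjusted p of 0.157 and 0.110.

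Immediate early and MAPK genes fell in 20 of 26 cases, with Nr4a1 2.34-fold and Egr1 2.06-fold lower, and Etv4 rose (camera adjusted p = 1.41e-11, adjusted p = 0.226 with an estimated correlation). Of the inflammatory list 14 of 30 members fell and 4, Vcam1, Ccl7, Il1rl1 and Csf1, rose (camera adjusted p = 2.42e-04, adjusted p = 0.457 with an estimated correlation). Lcn2 fell 3.51-fold, Il6 fell from 1986 ± 121 to 945 ± 56.9, and Ccl2 stood at 38811 ± 104 and 39677 ± 829, not called by limma (adjusted p = 0.401) but called higher under quantile scaling and library totals. Beside these, the macrophage marker Cd14 fell from 2992 to 1711 normalised reads. Interferon response genes fell in 9 of 36 cases, among them B2m and H2-D1 of antigen presentation, and 3 rose, Ifit2 and Irf1 among them (camera adjusted p = 0.0101, adjusted p = 0.206 with an estimated correlation), a call lost with a filter of 5 CPM, with 0.0791. Isg15 fell from 46.6 ± 2.85 to 23.4 ± 4.70, a limma call with an adjusted p of 0.00909 that was lost without PBS replicate 2 or MCF10A EV replicate 2, where its log2 change was -0.92 and -0.78.

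NRF2 targets rose in 15 of 22 cases, led by Nqo1, Txnrd1, Gclm and Hmox1, and Gstm1, Tkt and Sod2 fell (camera adjusted p = 2.62e-04, adjusted p = 0.257 with an estimated correlation). Nqo1, a quinone reductase, rose 1.48-fold from 1394 ± 22.9 to 2064 ± 32.2. Of 21 p53 targets 10 rose, such as Aen, a nuclease gene, and Ccng1, and Trp53inp1 fell (camera adjusted p = 0.00173, adjusted p = 0.287 with an estimated correlation). YAP and SRF targets rose in 10 of 20 cases, among them Amotl2 at 1.83-fold and Zyx, a focal adhesion gene, and Tead1 fell (camera adjusted p = 9.14e-05, adjusted p = 0.363 with an estimated correlation). Of 20 amino acid genes 11 rose and 6 fell, with the serine and glycine pathway genes Shmt1, Shmt2 and Psat1 1.90-fold, 1.41-fold and 1.23-fold higher (camera adjusted p = 0.0485, adjusted p = 0.534 with an estimated correlation). That call was lost without PBS replicate 2, either MCF10A EV library or either MDA-MB-231 EV library, with camera adjusted p from 0.0516 to 0.0651. It was also lost with filters of 10 normalised reads and of 5 CPM and by edgeR, with 0.0565, 0.0948 and 0.0598.

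Of 25 stress response genes 14 fell and 2, Chac1 and Ddit3, rose, with a median of -0.11 (camera adjusted p = 6.14e-04, adjusted p = 0.525 with an estimated correlation), and fry did not call the list, with 0.0643. Both of these are targets of the transcription factor ATF4. Collagens and fibrillar matrix genes fell in 15 of 33 cases, with Thbs1 1.57-fold and Plod2 1.70-fold lower, and Col3a1, Col12a1 and Col5a2 rose (camera adjusted p = 1.64e-05, adjusted p = 0.466 with an estimated correlation). Col3a1, a fibrillar collagen gene, rose 1.74-fold from 3968 ± 7.22 to 6885 ± 4.69, and Col1a1 fell from 56642 ± 662 to 50926 ± 294. TGF-beta response genes fell in 10 of 20 cases, with Ltbp2 and Skil among them, and 3 rose, with Id1 and Id3 among them (camera adjusted p = 0.00974, adjusted p = 0.226 with an estimated correlation). Vesicle biogenesis genes fell in 9 of 24 cases, among them Cd81 and Cd82, and Cd63 rose (camera adjusted p = 0.0134, adjusted p = 0.326 with an estimated correlation).

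The 8 largest rises were in Ptx3, Dctd, Nr1h5, Gpatch4, Dusp9, Shmt1, Calcrl and Dna2, from 2.36-fold in Ptx3, which encodes the soluble pattern recognition molecule pentraxin 3 and rose from 595 ± 37.6 to 1406 ± 100.3, to 1.89-fold in Dna2. The 8 largest falls were in Hp on chromosome 8, Lcn2 on chromosome 2, Tnn, Osbp2, Gngt2, Saa3, Plek and Nos2, from 3.61-fold in Hp, the haptoglobin gene, to 2.50-fold in Nos2, the inducible nitric oxide synthase gene. Acta2 rose from 1500.4 ± 149 to 2385 ± 115, 1.59-fold.

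Camera did not call the other 12 lists, with adjusted p from 0.0793 to 0.941. Contractile genes Acta2, Tpm2 and Myl9 rose and 6 fell, with a median and mean above 0 while the test pointed down. Of 20 proteases and inhibitors 7 fell, Mmp13 by 2.33-fold, and Ctsl, Mmp3, Adam12 and Timp1 rose. In oxidative phosphorylation Cycs, Ndufa4, Atp5b, Uqcrc2 and Ndufv1 rose and Cox6a1, Atp5e, Ndufa1, Cox4i1 and Atp5d fell. Of 24 lipid genes 7 fell, Lpl by 2.07-fold, and Angptl4, Fabp5, Acaca and Fasn rose. Of 14 heat shock genes 8 rose, and Bag3, Hspa1a and Hspa1b fell. Of 24 growth factors 8 fell and 5 rose, such as Angptl4, Angpt1, Figf and Vegfc. Of 27 autophagy and lysosome genes 7 fell and 3 rose, Ctsl and Lamp1 among them, and the median of -0.02 turned to 0.003 with library totals. Among the markers, Cdh1 and Esam were called higher at 2.35 and 5.72 normalised reads, near the floor, Cd14, Lipe and Des fell, and Nes and Ncam1 rose. The medians of the epithelial, macrophage and endothelial markers, -0.05, -0.06 and 0.03, changed sign with the scaling.

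In all, limma called 4764 of 15025 genes, 2571 higher and 2193 lower, of which 198 differed at least 2-fold, 38 higher and 160 lower. Those of at least 2-fold were 125 without PBS replicate 1, 42 higher and 83 lower, and 120 without PBS replicate 2, 46 higher and 74 lower. Without MCF10A EV replicate 1 or MCF10A EV replicate 2 the higher were 20 and 24. With a filter of 5 CPM those of at least 2-fold were 3 higher and 29 lower, and with DESeq2 they were 6 and 35. Under quantile scaling they were 62 and 128. Library totals gave 3194 higher and 2044 lower calls, 61.0% higher in place of 54.0%. Limma without trend called 2231 genes in all, and not Nr1h5, Rpl10 and Col1a1. Adjusted over the list alone, the counts of 7 called lists were the same as over all genes. In the other 11 they were 3 higher and 11 lower TGF-beta genes, 3 and 16 matrix, 5 and 15 inflammatory, 4 and 10 interferon, 0 and 7 ribosomal protein, 0 and 17 glycolysis, 11 and 7 amino acid, 3 and 14 stress, 11 and 2 p53, 16 and 3 NRF2 and 1 and 10 vesicle genes. Camera called 18 of 30 lists, and 0 with an estimated correlation, where 7 had an unadjusted p under 0.05, while fry called 21.

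**Figure D2:**
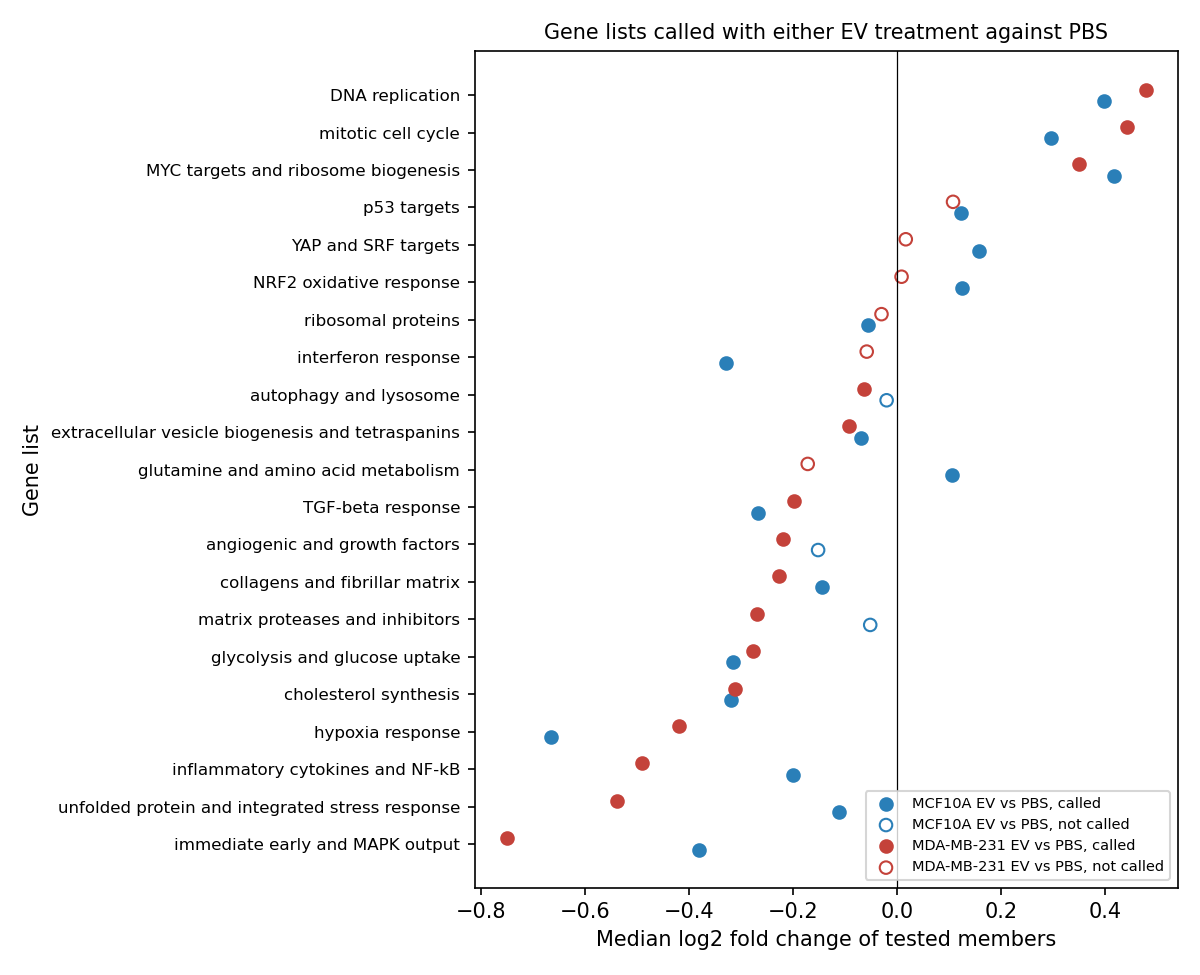
Median log2 fold change of the tested members (horizontal axis) of each gene list called with either EV treatment against PBS (vertical axis), in blue for MCF10A EVs and red for MDA-MB-231 EVs, filled where camera called the list with its preset correlation. DNA replication lies at 0.40 and 0.48 and immediate early and MAPK output at -0.38 and -0.75; medians changed sign with the scaling for interferon, ribosomal protein, YAP and SRF and autophagy genes with MDA-MB-231 EVs and for autophagy genes with MCF10A EVs.

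Both EV treatments moved many genes the same way against PBS. Of the 15025 genes, 1820 were called higher and 1471 called lower with both, where independent calls would give 460.0 and 371, and 78 were called in opposite directions. With library totals 2640 were called higher and 1297 lower with both, and with DESeq2's size factors 1811 and 1821. Dctd, a deaminase gene of thymidylate supply, and Nr1h5 were among the 8 largest rises with both EVs, and Plek and Tnn were among the 8 largest falls with both. The log2 changes correlated across genes with Pearson r = 0.607 and Spearman rho = 0.651, and 76.9% had the same sign; genes are not independent replicates. Both comparisons share the PBS libraries, and 50 simulations of unchanged groups gave a Pearson r of 0.499 (SD 0.013), a Spearman rho of 0.437 and 0 genes called in both. The observed covariance of 0.117 exceeded the simulated 0.0485 by 0.0684. The simulations drew each gene independently, so their SD leaves out deviations that genes share. With a different PBS library in each comparison, chosen after the results were seen, the covariance was 0.0633 and 0.0659 and the Pearson r 0.257 and 0.270. A difference that both PBS libraries had from the EV libraries remains in these values.

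The direct comparison of MDA-MB-231 with MCF10A EVs asks what differs after vesicles of a cancer line and of a non-tumorigenic line. The sample details used here give no EV dose, and each kind of vesicle came from a single line. The amount of vesicles and the identity of the line therefore cannot be told apart from cancer origin. Stress response, inflammatory and matrix protease transcripts were lower with MDA-MB-231 EVs, and mitotic and some hypoxia and interferon transcripts were higher. Chac1, a glutathione-degrading enzyme gene induced by ATF4, stood at 1437 ± 72.7 normalised reads with MCF10A EVs and 575 ± 24.2 with MDA-MB-231 EVs, 2.50-fold lower. Ptgs2 was 2.59-fold lower, at 31472 ± 2503 against 81439 ± 3082, and Il6 2.05-fold lower, at 461 ± 29.5 against 945 ± 56.9. Lox, the collagen cross-linking enzyme gene, was 1.63-fold higher, at 15820 ± 27.1 against 9684 ± 196.

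Of 25 genes of the unfolded protein and integrated stress response 24 fell and 0 rose, with a median log2 change of -0.47 (camera adjusted p = 4.99e-34, adjusted p = 0.205 with an estimated correlation). Hspa5 was 1.51-fold lower, at 34450 ± 1824 against 52040 ± 1714, and Manf and Hyou1 were 1.42-fold and 1.51-fold lower. Amino acid genes fell in 14 of 20 cases, with Mthfd2, Asns and Slc7a5 1.45-fold, 1.25-fold and 1.28-fold lower, and 0 rose (camera adjusted p = 1.38e-08, adjusted p = 0.218 with an estimated correlation). Inflammatory genes fell in 17 of 30 cases, and Saa3, Cxcl12, Lcn2 and Ccl8 rose (camera adjusted p = 2.55e-11, adjusted p = 0.242 with an estimated correlation). Lif was 1.92-fold, Csf3 1.67-fold and Ccl2 1.39-fold lower, and beside these Cd14 fell from 1711 to 977 and Csf1r from 80.8 to 27.6. Immediate early and MAPK genes fell in 15 of 26 cases and 0 rose, with Ier3 1.84-fold and Phlda1 1.68-fold lower (camera adjusted p = 1.61e-12, adjusted p = 0.218 with an estimated correlation). Matrix proteases and inhibitors fell in 12 of 20 cases, with Mmp3, Mmp10 and Mmp13 1.69-fold, 1.63-fold and 1.99-fold lower, and Adamts5 rose (camera adjusted p = 4.26e-07, adjusted p = 0.205 with an estimated correlation).

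Mitotic genes rose in 15 of 25 cases and 0 fell, with Bub1b 1.29-fold and Mki67 1.14-fold higher (camera adjusted p = 3.09e-10, adjusted p = 0.205 with an estimated correlation). DNA replication genes rose in 6 of 26 cases, with a median of 0.09 and Mcm7 1.16-fold higher (camera adjusted p = 6.16e-04, adjusted p = 0.205 with an estimated correlation). Interferon response genes rose in 8 of 36 cases, such as Parp14, Ifit2 and B2m, and H2-D1 and H2-K1 fell (camera adjusted p = 0.00178, adjusted p = 0.205 with an estimated correlation). Hypoxia genes rose in 8 of 19 cases, with Bnip3 and Pdk1 1.44-fold and 1.34-fold higher, and Vegfa, Errfi1, Ero1l and Adm fell (camera adjusted p = 8.35e-04, adjusted p = 0.368 with an estimated correlation). Of 23 glycolysis genes 7 rose and 0 fell (camera adjusted p = 2.49e-04, adjusted p = 0.344 with an estimated correlation). Slc2a1 stood at 5062 ± 44.2 and 5346 ± 242 (limma, adjusted p = 0.148), and was called higher without MDA-MB-231 EV replicate 2, with a log2 change of 0.12, and under quantile scaling, with library totals or by edgeR with the replicate block.

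Collagens and fibrillar matrix genes fell in 18 of 33 cases, with Tnc 1.84-fold lower, and Lox, Plod2, Bgn, Fbln2 and Col1a2 rose (camera adjusted p = 7.31e-05, adjusted p = 0.414 with an estimated correlation). Col1a1 stood at 50926 ± 294 and 48206 ± 1478 (limma, adjusted p = 0.0626), and was called lower without MDA-MB-231 EV replicate 1, with a log2 change of -0.11. It was also called lower with the replicate block, with each of 3 stricter filters, by limma-voom and by edgeR except with library totals, but its change was 0.01 under quantile scaling. Growth factor genes fell in 13 of 24 cases, with Igfbp5 and Angptl4 2.72-fold and 1.59-fold lower, and Figf and Vegfb rose (camera adjusted p = 7.31e-05, adjusted p = 0.218 with an estimated correlation). NRF2 targets fell in 12 of 22 cases, such as Srxn1, Txnrd1 and Hmox1, and Gstm1, Gsta4 and Ftl1 rose (camera adjusted p = 0.00149, adjusted p = 0.315 with an estimated correlation). The ferritin gene Fth1 fell 1.14-fold, but its log2 change was 0.05 under quantile scaling, where the list's call was lost with a camera adjusted p of 0.0901. Of 21 p53 targets 8 fell, among them Plk2, Cdkn1a and Sesn2, and Gtse1, a negative regulator of p53, rose (camera adjusted p = 0.00105, adjusted p = 0.290 with an estimated correlation). YAP and SRF targets fell in 8 of 20 cases, with Cyr61 1.57-fold lower, and 0 rose (camera adjusted p = 3.19e-04, adjusted p = 0.344 with an estimated correlation). That call was lost under quantile scaling, with a camera adjusted p of 0.0525. Of 27 genes of MYC targets and ribosome biogenesis 11 fell, such as Odc1 and Srm of polyamine synthesis, and Mxi1 and Cdk4 rose (camera adjusted p = 0.00193, adjusted p = 0.414 with an estimated correlation), and fry did not call the list, with 0.0621. Myc fell from 1624 ± 48.4 to 1420.3 ± 33.7 (limma, adjusted p = 0.00515), a call lost without MCF10A EV replicate 2, where its log2 change was -0.16, and by limma without trend (adjusted p = 0.108).

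Autophagy and lysosome genes fell in 11 of 27 cases, with Sqstm1 and Ctsl among them, and Ulk1 and Atg12 rose (camera adjusted p = 0.00178, adjusted p = 0.344 with an estimated correlation). Vesicle biogenesis genes fell in 6 of 24 cases, with Cd9 and Cd63 1.24-fold and 1.17-fold lower, and Flot1 rose (camera adjusted p = 0.0436, adjusted p = 0.344 with an estimated correlation). That call was lost without MCF10A EV replicate 1 and without MDA-MB-231 EV replicate 2, with camera adjusted p of 0.0605 and 0.101, and under quantile scaling, with 0.165. It was also lost with filters of 5 and 10 normalised reads and of 5 CPM and by edgeR, with 0.0691, 0.0743, 0.0926 and 0.0772.

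The 8 largest rises were in Cxcl12, Hp, Sned1, Bmf, L1cam, Nhsl1, Col4a6 and Ranbp3l, from 2.21-fold in Cxcl12 to 1.69-fold in Ranbp3l. Hp stood at 675 ± 10.1 with MCF10A EVs and 1422 ± 37.6 with MDA-MB-231 EVs. The 8 largest falls were in Plek, Igfbp5, Ptgs2, Chac1, Csf2, Ankk1, Stfa3 and Olr1, from 4.19-fold in Plek to 2.21-fold in Olr1, the gene of an oxidised lipoprotein receptor. Acta2 fell from 2385 ± 115 to 1919 ± 23.5. Isg15 stood at 23.4 ± 4.70 and 26.0 ± 0.870 (limma, adjusted p = 0.742), with a log2 change of 0.16 that was -0.04 without MCF10A EV replicate 2.

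Camera did not call the other 12 lists, with adjusted p from 0.0586 to 0.805. TGF-beta response genes Tgfbr1, Ltbp2, Tgfb3, Skil and Id2 rose and 5 fell, such as Tgfbi, Ltbp1, Inhba and Id3. Contractile genes Pdgfra and Pdgfrb rose and Pdpn, Tpm1, Acta2 and Thy1 fell, and the mean differed in sign from the median and the test. Of 20 cholesterol genes 3 rose, such as Mvk and Idi1, Idi1 not without MCF10A EV replicate 2, where its log2 change was 0.12, and 1 fell, again with a mean that differed in sign from the median and the test. Of 24 lipid genes 6 fell and Fabp5 and Elovl6 rose, and of 14 heat shock genes Hsph1, Hspa4l and Chordc1 fell and 0 rose. The medians of the contractile, cholesterol, lipid and heat shock lists changed sign with the scaling. Of 33 ribosomal protein genes limma called 0, with 2 at an unadjusted p under 0.05, edgeR called 2 and limma under quantile scaling called 11, all higher. In oxidative phosphorylation Cox5a, Sdha and Uqcrc1 rose and Uqcrq and Cycs fell, but Sdha was lost without MCF10A EV replicate 1, at 0.13, and Uqcrc1 without MCF10A EV replicate 2 or MDA-MB-231 EV replicate 1, at 0.11 and 0.13. Of the markers Cd14, Csf1r, Cdh5 and Lipe fell, Plin4, Map2 and Ncam1 rose, and limma called 0 of 10 epithelial markers, with 2 at an unadjusted p under 0.05, and edgeR called 0 of 5. The mean of the adipocyte markers differed in sign from their median and test.

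In all, limma called 2541 of 15025 genes, 1027 higher and 1514 lower with MDA-MB-231 EVs, of which 133 differed at least 2-fold, 61 higher and 72 lower. Those of at least 2-fold were 72 without MCF10A EV replicate 1, 30 higher and 42 lower, and 85 without MDA-MB-231 EV replicate 2, 30 higher and 55 lower, while without MDA-MB-231 EV replicate 1 the higher were 39. With a filter of 5 CPM those of at least 2-fold were 3 higher and 17 lower, and with DESeq2 they were 21 and 33. Higher calls made up 40.4%, against 50.7% (1244 higher, 1209 lower) under quantile scaling and 63.2% (2029 higher, 1179 lower) with library totals. Without MCF10A EV replicate 1, MCF10A EV replicate 2 or MDA-MB-231 EV replicate 2 the count of all calls was 1425, 1668 and 1646, and it was 378 by limma without trend, 124 higher and 254 lower, and 1567 by DESeq2. Of the genes above, limma without trend did not call L1cam, Nhsl1, Col4a6 and Ranbp3l among the largest rises, Stfa3 among the largest falls, or Acta2, Mki67, Vegfa, Mcm7, H2-D1, B2m, Parp14, Ifit2, Asns, Slc7a5, Odc1, Srm, Txnrd1, Hmox1, Fth1, Ctsl, Cd9, Cd63, Tpm1, Pdgfra, Hspa4l, Idi1, Sdha and Uqcrc1. Adjusted over the list alone, the counts were the same in matrix protease and amino acid genes and in p53 targets. Over the list alone they were 6 higher and 19 lower in matrix genes, 4 and 18 inflammatory, 11 and 2 interferon, 20 and 0 mitotic, 8 and 0 replication, 2 and 12 MYC and 8 and 0 glycolysis genes. They were also 9 and 4 hypoxia, 0 and 25 stress, 5 and 14 NRF2, 0 and 20 immediate early, 1 and 11 YAP and SRF, 3 and 14 growth factor, 2 and 12 autophagy and 1 and 9 vesicle genes. Camera called 18 of 30 lists, and 0 with an estimated correlation, where 6 had an unadjusted p under 0.05, while fry called 20.

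**Figure D3:**
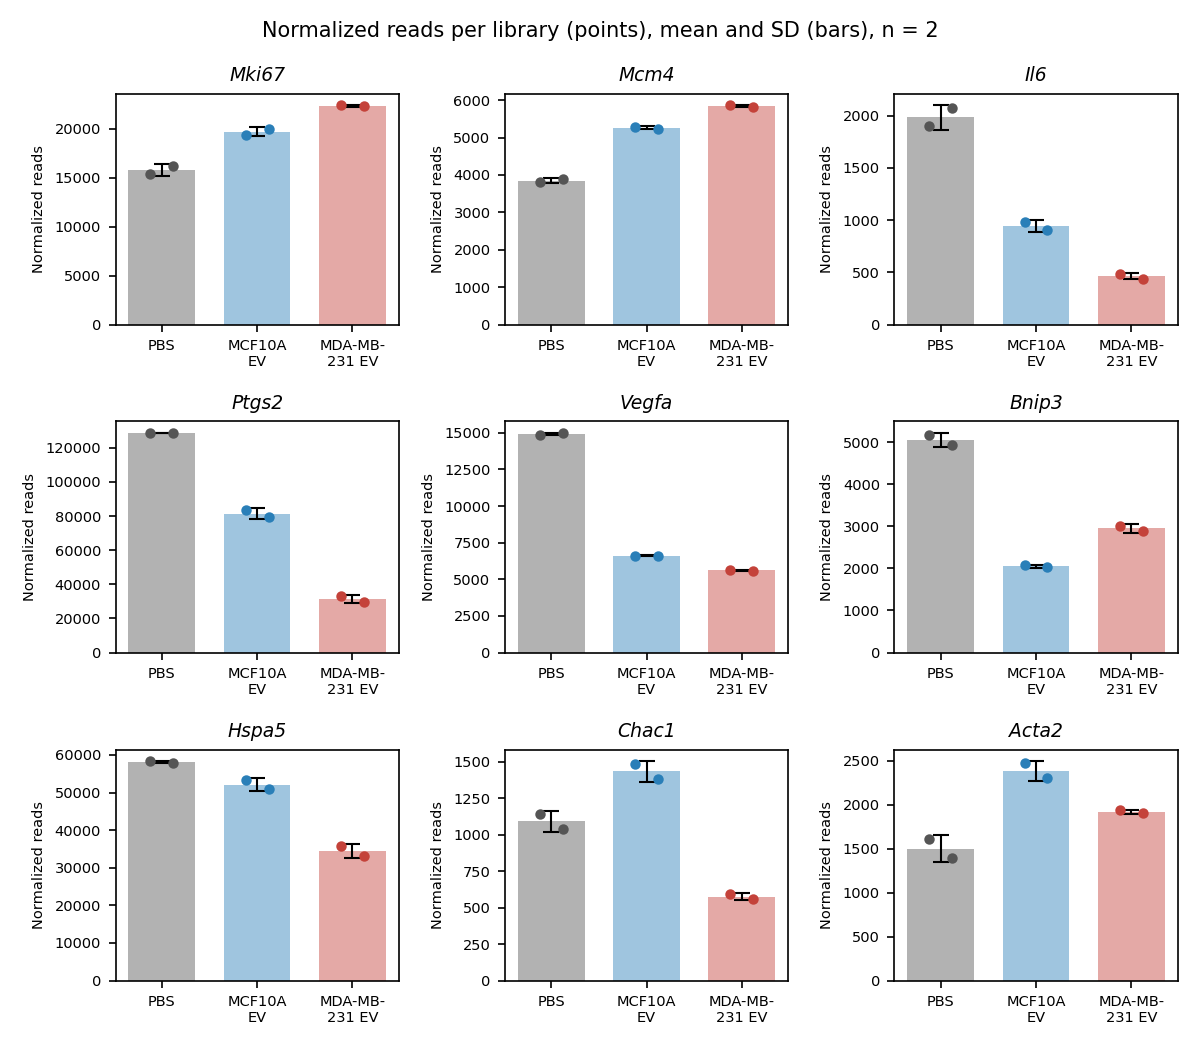
Normalised reads (vertical axes, from 0) of 9 genes by treatment, with a point per library, bars at the mean and error bars of 1 SD, n = 2. Chac1 stood at 1091 with PBS, 1437 with MCF10A EVs and 575 with MDA-MB-231 EVs, while Il6 stood at 1986, 945 and 461.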

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

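Of the tests in this part, those on the split of the PBS libraries, on the scaling of the libraries and on trends with GC content, transcript length and level were chosen only after the results were seen. The simulation of the shared controls was planned, but its use for the first pattern, and the limit it was read against, were set after the results were seen.

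Limma called 78 genes in opposite directions with both EVs against PBS, but 27 without PBS replicate 1, 31 without PBS replicate 2, 45 without MCF10A EV replicate 1, 86 without MDA-MB-231 EV replicate 1 and 15 by limma without trend. All 78 were also called between the EVs, which follows from opposite calls against the same PBS libraries and adds no evidence. Chac1 stood at 1091 normalised reads with PBS, 1437 with MCF10A EVs and 575 with MDA-MB-231 EVs, and its log2 difference between the EVs was -1.32. Adam12, a metalloprotease gene, stood at 403, 538 and 312, a difference of -0.78. Mmp3, the stromelysin gene, stood at 31943, 36081 and 21375, a difference of -0.76. Cspg4, a chondroitin sulfate proteoglycan gene, stood at 895, 724 and 1222, a difference of 0.75.

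The first pattern is that mitotic and DNA replication genes were higher, and inflammatory, immediate early and hypoxia genes lower, with both EV treatments than with PBS. The covariance of both effects lay 33.5 SDs above that of simulated unchanged groups, in which each gene was drawn independently. This argues against shared PBS noise that is independent between genes, over all genes. It cannot decide on PBS deviations that genes share, which the simulated SD leaves out, or on the 5 lists alone. When each EV treatment was compared with a different PBS library, 0 of the 5 lists changed the sign of their median. That argues against a deviation of a single PBS library. The scaling of the libraries moves genes alike, so a factor per library cannot by itself give both directions. The medians of the rising lists lay at least 0.467 above those of the falling lists on the log2 scale. These lists were chosen from the same data for their directions, so that distance restates the pattern and is no independent test. After trends on GC content, length and level were removed, 5 of 5 lists kept their camera call at the preset correlation in both comparisons. With an estimated correlation, however, 0 of them were called on the unaltered changes. Those trends explained 0.138% and 1.66% of the variance of the changes. An effect of EVs of either source on these gene groups is left as a hypothesis from the same data. A difference between the PBS and EV cultures in density, medium or handling stays open and untested, because it would be confounded with the treatment.

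The second pattern is that stress response genes were lower with MDA-MB-231 than with MCF10A EVs. The list's median minus that of all tested genes was -0.461 at its nearest to 0, which argues against the scaling of the libraries. The list was picked from the same data, so that distance is no independent test. After the trends on GC content, length and level were removed the median was -0.45, against -0.47 before. Of the 25 genes limma called 24 lower, and 22 without MCF10A EV replicate 1. A difference in the EVs' cargo or amount is a candidate explanation that was not tested. A difference between the cultures cannot be excluded, since each group's libraries might share a culture.

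The third pattern is that some inflammatory transcripts that leukocytes also make, such as Cd14, Il1b and Plek, fell with both EV treatments. These examples were picked from the same data, and other inflammatory genes, such as Vcam1 and Ccl7, rose with MCF10A EVs. RNA from macrophages in the PBS cultures is argued against by the summed level of Ptprc, Csf1r, Lyz2, Laptm5 and Tyrobp, 2.74% of that of Cd14, Il1b and Plek. With PBS, Csf1r stood at 78.5 and Lyz2 at 17.2 normalised reads and the other 3 markers at 0, against 2992 for Cd14, 241 for Il1b and 261 for Plek, and 6 of the 15 macrophage markers passed the filter. For the inflammatory list as a whole, the scaling of the libraries stays open with MCF10A EVs. There the list's median minus that of all tested genes was -0.179 at its nearest to 0, with 95% of 2000 resamplings of its members between -0.415 and 0.0128. That list does not hold Cd14, Il1b or Plek, so its median cannot decide on them. With MCF10A EVs they stood at 1711, 183 and 103 normalised reads. The other scalings shifted the log2 changes of MCF10A EVs against PBS by a median of -0.0146 to 0.0231. A fall of these transcripts within the fibroblasts may explain the pattern, and a culture difference stays open here too.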

How the results depend on the processing

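The tests on recovered reads, the filters of 10 normalised reads and 5 CPM and the block with the estimated correlation were chosen only after the results were seen. For MDA-MB-231 EVs against PBS, MCF10A EVs against PBS and MDA-MB-231 against MCF10A EVs, limma without trend called 3346, 2231 and 378 genes and 1642 the same way in both EV effects, and a 2-fold minimum left 320, 198 and 133. DESeq2 called 1567 genes between the EVs, and a filter of 5 CPM left 98, 32 and 20 at least 2-fold. Camera called 15, 18 and 18 lists with the preset correlation and 0, 0 and 0 with an estimated one, with or without the replicate block. The estimate allows for members that vary together, which widens the null, but without the block it rests on 3 residual degrees of freedom. Whether co-varying members or so few degrees of freedom removed the calls was not tested. The correlation of both EV effects, 0.607, was 0.703 with a filter of 10 normalised reads, 0.795 with 5 CPM, 0.760 with DESeq2 and 0.70 with limma-voom. All of these tested fewer genes, and the cause was not tested.

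Leaving out each library in turn gave 4018 to 5056, 3370 to 4897 and 1425 to 2257 genes, 15 to 18, 17 to 18 and 18 to 20 lists, 2402 to 3099 genes called the same way in both and correlations of 0.516 to 0.691. With the replicate block the counts were 5187, 4746 and 2560 genes, 16, 18 and 18 lists and 3270 genes the same way. Between the EVs, 3 values turned. The log2 change of Fth1 went to 0.0493 and of Col1a1 to 0.0082 under quantile scaling, and that of Isg15 ranged from -0.0386 without MCF10A EV replicate 2 to 0.3567 without MCF10A EV replicate 1, and the cause was not tested. Of 6044 comparisons of a named gene's result with an alternative, 5941 kept direction and side of the threshold, 85 lost the call, 15 gained it and 3 turned. Limma without trend gave 61 of the losses. Most named genes were picked for large changes or small p in the same data, which favours keeping the call. Some alternatives reuse the same log2 change, so direction could not turn there. Over all genes, limma without trend kept 313 of the 2541 calls between the EVs with the same sign. Of 816 comparisons for called lists 692 kept the call, 124 lost it and 0 turned, and 102 of the losses came from the estimated correlation. Of the other 22, 7 came from leaving out a library, 6 from filters, 4 from quantile scaling, 3 from fry and 2 from edgeR.

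Depth limited the marker genes with few or no reads, since 3 reads, or 0.102 to 0.134 CPM, were taken as an approximate upper bound behind a count of 0.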

Other observations

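The 7 lists in this part and the test on the stress response arms were chosen only after the results were seen, so their p-values, adjusted over 21 tests, describe these samples and give no independent evidence.

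Several further gene groups differed between the EVs, of which 2 of 11 interleukin-1 family genes and 2 of 16 prostaglandin genes are also in the fixed inflammatory list. Aminoacyl-tRNA synthetases, which charge tRNAs and include ATF4 targets, rose in 17 of 20 cases with MCF10A EVs against PBS (camera adjusted p = 2.84e-09, adjusted p = 0.210 with an estimated correlation). Between the EVs 14 fell with MDA-MB-231 EVs (camera adjusted p = 4.77e-10, adjusted p = 0.210 with an estimated correlation), and against PBS 6 rose and 3 fell (camera adjusted p = 0.386, adjusted p = 0.792 with an estimated correlation). Interleukin-1 family genes fell in 7 of 11 cases with MDA-MB-231 EVs against PBS (camera adjusted p = 1.03e-07, adjusted p = 0.210 with an estimated correlation) and in 7 with MCF10A EVs, where 1 rose (camera adjusted p = 5.52e-04, adjusted p = 0.304 with an estimated correlation). Between the EVs 8 fell (camera adjusted p = 3.33e-10, adjusted p = 0.210 with an estimated correlation). Il33, an alarmin gene, stood at 19458 normalised reads with PBS, 13991 with MCF10A EVs and 8564 with MDA-MB-231 EVs, and the receptor antagonist Il1rn at 2146, 939 and 703. Prostaglandin synthesis and receptor genes fell in 6 of 13 cases with MDA-MB-231 EVs and 3 rose (camera adjusted p = 0.00738, adjusted p = 0.313 with an estimated correlation), against 5 and 3 with MCF10A EVs (camera adjusted p = 0.446, adjusted p = 0.792 with an estimated correlation). Between the EVs 6 fell (camera adjusted p = 1.21e-05, adjusted p = 0.210 with an estimated correlation), with Pla2g4a, the phospholipase gene that releases arachidonic acid, at 10041, 8707 and 5705.

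Replication-dependent histone genes, whose near-identical copies share reads, rose in 19 of 67 cases and fell in 2 with MDA-MB-231 EVs against PBS (camera adjusted p = 2.35e-04, adjusted p = 0.313 with an estimated correlation). With MCF10A EVs 15 rose and 11 fell (camera adjusted p = 0.905, adjusted p = 0.965 with an estimated correlation), and between the EVs 21 were higher with MDA-MB-231 EVs (camera adjusted p = 1.18e-10, adjusted p = 0.210 with an estimated correlation). Of 13 clock genes 5 rose and 4 fell with MDA-MB-231 EVs (camera adjusted p = 0.905, adjusted p = 0.948 with an estimated correlation), 1 rose and 6 fell with MCF10A EVs (camera adjusted p = 0.0639, adjusted p = 0.245 with an estimated correlation), and 4 were higher and 1 lower between the EVs (camera adjusted p = 0.0413, adjusted p = 0.220 with an estimated correlation). Arntl stood at 1534, 989 and 890 and Per3 at 179, 205 and 306.

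ATF4 targets rose in 12 of 24 cases and fell in 7 with MCF10A EVs against PBS (camera adjusted p = 0.0759, adjusted p = 0.616 with an estimated correlation), while endoplasmic reticulum chaperones fell in 12 of 21 cases and rose in 1 (camera adjusted p = 2.46e-04, adjusted p = 0.327 with an estimated correlation). With MDA-MB-231 EVs 17 ATF4 targets fell and 5 rose (camera adjusted p = 4.27e-06, adjusted p = 0.254 with an estimated correlation), and 19 chaperones fell (camera adjusted p = 8.05e-19, adjusted p = 0.210 with an estimated correlation). Between the EVs 20 targets and 19 chaperones were lower with MDA-MB-231 EVs (camera adjusted p = 6.58e-16, adjusted p = 0.210 with an estimated correlation for the targets and camera adjusted p = 1.89e-27, adjusted p = 0.210 with an estimated correlation for the chaperones). The stress list holds 6 of the 25 ATF4 targets listed and 16 of the 21 chaperones. The hypothesis that MCF10A EVs may move both arms of the stress response apart was tested by the difference of their medians, 0.22 on the log2 scale, with ATF4 targets higher. That difference has no p-value of its own. At the preset correlation camera called the chaperones but not the ATF4 targets, of which 7 fell with MCF10A EVs. The difference therefore leaves open whether the arms moved apart.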
